A study of Mus musculus with 11 samples.

How the data were processed

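Transcript levels were measured in mouse cells and tissue with Affymetrix mouse genome arrays, 1 array per sample and 11 arrays in all. According to the labels' protocols, total RNA was purified with Trizol and a column kit, and close to 50 ng per sample went through 2 rounds of amplification before biotin labelling. The first round was primed with oligo(dT) and the second with random primers, so the signal leans to the 3' end of transcripts.

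The deposited values are log2 intensities per probe set, made by the authors with RMA per the submitters' processing notes. RMA subtracts background, gives all arrays the same distribution of probe intensities and summarises each probe set on a log2 scale. Its version is not given in the sources used here. A change that moved most transcripts the same way would be removed by that step, so every fold change below is relative to the bulk of the transcripts on the same array. The values carry no detection calls. A level near the array median, which lay between 4.66 and 4.84, cannot be told from background, and a fold change that ends there understates the change. The number of arrays limits the precision, since a group holds 2 or 3.

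Samples were put in 4 groups from their titles and strain labels: the C57BL/6J cell line (3 arrays), C57BL/6J tissue (2 arrays), the tsA58 cell line (3 arrays) and tsA58 tissue (3 arrays). The titles call the replicates biological, while the series text speaks of several arrays per sample. Nothing states that the arrays came from separate cultures or animals. Sex-linked genes differ between arrays of each tissue group, so the tissue arrays are not all repeats of 1 sample. For the lines the spread that p-values rest on may be technical. Replicate numbers were not used to pair arrays.

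Of the 45101 probe sets, 64 are controls, 34945 carried 1 gene symbol in the platform's annotation table, 932 carried several and 9160 none. A probe set with several symbols or none was given no name. The Entrez identifiers of 34741 probe sets were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed through it. No genome sequence was used, and no coordinates are given. Each of the 18193 named genes was represented by its probe set with the highest mean over the 11 arrays. Genes above the array's median over all probe sets on at least 2 arrays were tested, which left 13285. Genes named here are those of single probe sets, and other probe sets of the same gene can differ. Of the 223 called results among the genes chosen for reporting, 102 had another probe set above the filter and in 95 all such probe sets had the same sign.

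Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 model with 4 group means, which had 7 residual and 3.49 prior degrees of freedom. The 5 comparisons were each line against the tissue of its strain, the lines with each other, the tissues with each other, and the difference between the line-tissue differences. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison. A gene was called when its adjusted p was below 0.05 and its change at least 2-fold. The spread of a gene is shared by all 4 groups, so arrays outside a comparison can change its standard errors and calls. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

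Before the data were examined, 27 gene lists with 387 entries were fixed, which cover markers of the cell types of the stomach wall, of progenitors and of other cells a dissection could carry, and pathways bearing on growth, stress, interferon, metabolism and signalling. A single-symbol probe set was found for 359 entries and 344 were tested. The 25 lists with at least 4 tested genes, apart from the sex and strain check genes, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation, and fry, were run beside it. With an estimated correlation 0 of 125 tests were called, even where all tested members of a list were called the same way. A list call lost under it therefore does not tell which lists change. Members were also counted with p-values adjusted over the list alone.

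The rule for naming genes was fixed at the same time. It takes the 5 called genes with the highest and the 5 with the lowest fold change, up to 3 called members of each list with the largest change, a fixed set of markers of interstitial cells and their progenitors, and the sex and strain check genes. Uncharacterised gene models were passed over. From what the rule gave, 260 results of a gene in a comparison were chosen for the stability checks, and that choice and the smaller choice printed below were made after the fold changes of the fit had been seen. The counts of stable results cover all 260, printed or not. Genes of the fixed marker set and check set without a single-symbol probe set are not reported here.

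The gene test was tried on simulated data in which 67 genes were changed by 2-fold, 67 by 4-fold and 66 by 8-fold. Of the 8-fold changes it recovered 97.0% in the C57BL/6J line against tissue, 100% in the tsA58 line against tissue, 95.5% between lines, 97.0% between tissues and 95.5% in the difference of differences. Of the 2-fold changes it recovered 13.4%, 31.3%, 38.8%, 16.4% and 11.9% in the same order, with 4 to 8 false calls among the unchanged of 13285 genes. A call needs an estimate of at least 2-fold, which a true 2-fold change often misses. Far fewer genes were changed than were called in the data, so the adjustment of p-values was stricter in the simulation. In 50 simulations of the comparison between lines, the list test called a list raised by 2-fold 50 times and an unchanged list 1 time in 1200. The simulated genes varied independently, with the same spread in all groups and no array standing apart. These rates therefore do not give the error on real lists, whose genes can vary together.

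Alternatives fixed before the data were examined were other ways to combine probe sets, no filter and a stricter filter at the 75th percentile, median centring, quantile normalisation, cyclic loess, centring on the hybridisation controls, an intensity trend, array weights, a fit of only the groups compared, other thresholds, a 3' to 5' covariate, the replicate number as a block, and each replicate left out in turn. Leaving out the 2 arrays that stood apart from their groups was added after the data were seen.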

Results

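The study profiled clonally derived cell lines of progenitors of interstitial cells of Cajal (ICC), the Kit-positive pacemaker cells of the gut wall, and the stomach muscle wall they were derived from. The C57BL/6J line (2xSCS2F10) came from wild-type mice and was grown at 37 °C in neural stem cell proliferation medium with 5% chick embryo extract. The tsA58 line (2xSCS70) came from H-2Kb-tsA58 mice, which carry a thermolabile SV40 large T antigen under an interferon-inducible promoter, and was grown in the same base medium at 39.5 °C without interferon-gamma. For it the labels name no extract. The source tissue of both strains was the gastric tunica muscularis, the muscular layers of the stomach. There were 3 arrays of each line, 2 of C57BL/6J tissue and 3 of tsA58 tissue. Below, fold changes are on the log2 scale with their standard errors, and levels are log2 intensities with their SD over the arrays of a group.

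Replicate arrays correlated at 0.986 to 0.991 in the C57BL/6J line, 0.982 in C57BL/6J tissue, 0.956 to 0.988 in the tsA58 line and 0.964 to 0.976 in tsA58 tissue, across probe sets, which are not independent. The first principal component held 62.0% of the variance and separated lines from tissues, and the second held 15.2%. On it, tsA58 line replicate 3 lay at 19, against 62.7 and 67.5 for replicates 1 and 2. The log2 ratio of 3' to 5' actin control probe sets was 1.02 ± 0.02 in the C57BL/6J line, 0.93 ± 0.12 in C57BL/6J tissue, 0.47 ± 0.40 in the tsA58 line and 0.44 ± 0.03 in tsA58 tissue. The hybridisation controls averaged 9.63 ± 0.29, 10.86 ± 0.13, 8.14 ± 0.19 and 8.74 ± 1.10 in the same order. The poly-A spikes averaged 5.00 ± 0.11, 8.28 ± 0.34, 4.66 ± 0.17 and 6.53 ± 1.53. RNA input or array processing thus differed with strain and between lines and tissues, and cannot be told apart from either. Centring the arrays on the hybridisation controls moved the median fold change of all genes by 1.23 in the C57BL/6J line against tissue, 0.60 in the tsA58 line against tissue, 1.49 between lines, 2.13 between tissues and -0.64 in the difference of differences.

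**Figure D1:**
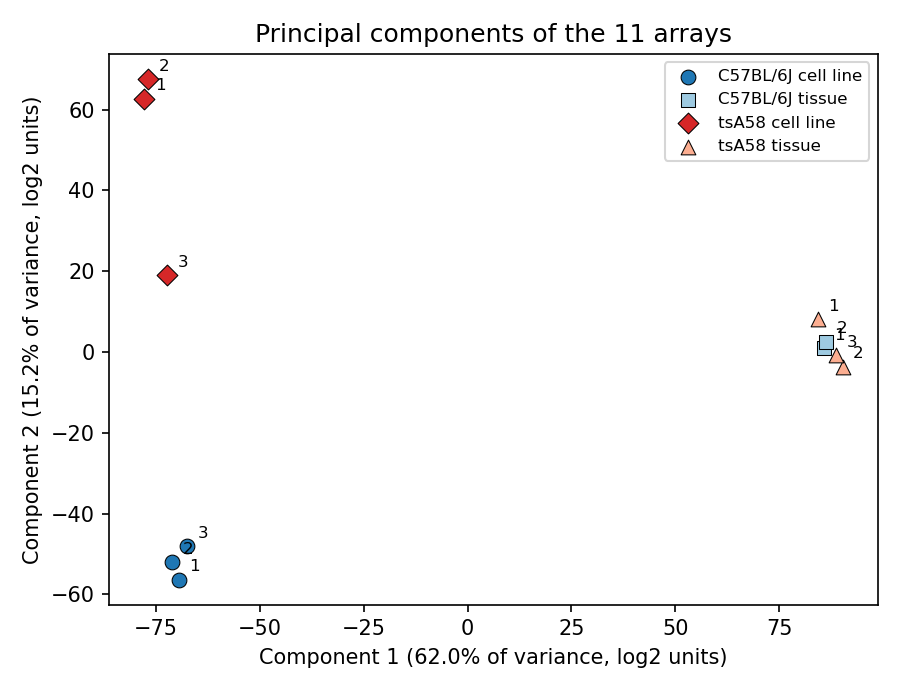
Scores of the 11 arrays on the first (x axis, 62.0% of the variance) and second (y axis, 15.2%) principal components of the log2 intensities of the genes tested; each point is an array, numbered by replicate, with colour and shape by group. Lines and tissues lie apart on component 1, and tsA58 line replicate 3 lies at 19 on component 2 while replicates 1 and 2 lie at 62.7 and 67.5.

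The C57BL/6J line was compared with C57BL/6J stomach muscle to see how a cultured progenitor line differs from its source. The line had lower levels of most listed genes of differentiated smooth muscle, enteric neurons and gastric epithelium, lists that lost their calls with an estimated correlation (adjusted p = 0.246, 0.246 and 0.347). Smooth muscle gamma-actin (Actg2) stood at 3.51 ± 0.22 in the line (n = 3) and 12.34 ± 0.05 in tissue (n = 2), a fold change of -8.83 ± 0.20 (adjusted p = 1.54e-09). The smooth muscle myosin heavy chain Myh11 changed by -7.92 ± 0.21. The neuropeptide genes Vip (-7.46 ± 0.20) and Tac1 (-7.43 ± 0.23) and the receptor Ret (-6.88 ± 0.25) were lower, as were the gastrokines Gkn2 (-8.60 ± 0.40) and Gkn1 (-7.65 ± 0.38), which gastric surface cells secrete. The collagenase Mmp13 (9.19 ± 0.25, adjusted p = 3.25e-09) and the metalloproteinase inhibitor Timp1 (6.34 ± 0.51) were higher in the line. In all, 4530 of 13285 genes were called, 2326 higher and 2204 lower (5148 and 723 with centring on the hybridisation controls).

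Of 20 smooth muscle genes tested in the C57BL/6J line against tissue, 16 were lower and 0 higher (17 lower when adjusted over the list alone; camera adjusted p = 5.18e-12, but adjusted p = 0.246 with an estimated correlation). All 18 enteric neuron genes were lower, over all genes and when adjusted over the list alone (median -4.53; adjusted p = 0.246 with an estimated correlation). Of 11 glial genes 7 were lower, Fabp7 (-7.55 ± 0.46) and Sox2 (-5.27 ± 0.23) among them, and again 7 when adjusted over the list alone (adjusted p = 0.264 with an estimated correlation). Of 17 macrophage and leukocyte genes 13 were lower and 1 higher (15 and 1 when adjusted over the list alone; adjusted p = 0.279 with an estimated correlation), with the mannose receptor Mrc1 at -4.63 ± 0.30. Endothelial genes were lower in 8 of 12 (8 when adjusted over the list alone; adjusted p = 0.279 with an estimated correlation), for example the angiopoietin receptor Tek (-3.01 ± 0.35). Gastric epithelial genes were lower in 13 of 17, and in 13 when adjusted over the list alone (camera adjusted p = 0.347 with an estimated correlation). That list averaged 10.11 ± 0.08 in C57BL/6J tissue.

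Of 9 markers of mature ICC, 6 were lower in the C57BL/6J line and 0 higher (the same counts when adjusted over the list alone; median -1.22; adjusted p = 0.246 with an estimated correlation). The receptor Kit was at -3.55 ± 0.37, while its other probe set gave -0.65 and was not called. Its level in the line, 3.60 ± 0.26, lay below the array median. The chloride channel Ano1 was at -3.66 ± 0.37. Kit ligand (Kitl) was lower (-3.04 ± 0.26), although 1 of its 3 other probe sets above the filter gave 0.30. Of the 5 ICC progenitor markers, which include Kit, Cd44 was higher (1.17 ± 0.29), a call that ended without C57BL/6J tissue replicate 1 (1.03, adjusted p = 0.068). Igf1r was lower (-1.23 ± 0.35), which ended without tissue replicate 1 (-1.24, adjusted p = 0.074) or 2 (-1.23, adjusted p = 0.075). Cd34 (-0.14 ± 0.35) and Insr (0.18 ± 0.44) were not called. Outside that list, Pdgfra (-0.68 ± 0.62), a receptor of interstitial fibroblast-like cells, was not called. When arrays were centred on the hybridisation controls, Igf1r came to 0.000134 and Cd34 and Pdgfra turned to 1.09 and 0.56, and under cyclic loess Insr turned to -0.17. Other probe sets gave up to 0.47 for Igf1r and 0.31 to 0.81 for Pdgfra. The progenitor list thus had 1 higher member, Cd44, and 2 lower, Kit and Igf1r, the same when adjusted over the list alone (camera adjusted p = 0.493).

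Fibroblast and matrix genes were lower in 9 of 19 and higher in 1 in the C57BL/6J line (the same counts when adjusted over the list alone; median -1.11; camera adjusted p = 0.0031, but adjusted p = 0.405 with an estimated correlation), with the matrix proteins lumican (Lum, -7.92 ± 0.34) and dermatopontin (Dpt, -7.91 ± 0.48) the furthest down. Wnt and hedgehog genes were lower in 6 of 12 (6 when adjusted over the list alone; adjusted p = 0.264 with an estimated correlation), led by the secreted Wnt antagonist Sfrp1 (-6.26 ± 0.23). When arrays were centred on the hybridisation controls, the medians of the fibroblast, Wnt and hedgehog, and ICC lists turned to 0.13, 0.07 and 0.02. Glycolysis genes were higher in 13 of 17 (13 when adjusted over the list alone; median 1.65; adjusted p = 0.405 with an estimated correlation), including hexokinase 2 (Hk2, 2.86 ± 0.27) and the lactate exporter Slc16a3 (3.16 ± 0.43). Cholesterol synthesis genes were higher in 9 of 15 (9 when adjusted over the list alone; median 1.24; adjusted p = 0.563 with an estimated correlation), for example Msmo1 (2.05 ± 0.33). Exocrine pancreas genes, which mark tissue carried along in dissection, were lower in 4 of 8 (4 when adjusted over the list alone; adjusted p = 0.563 with an estimated correlation), and without C57BL/6J tissue replicate 1 the camera adjusted p was 0.115. In C57BL/6J tissue that list averaged 9.03 ± 3.39.

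In the C57BL/6J line the cell cycle inhibitors Cdkn2a (3.51 ± 0.44) and Cdkn2b (3.20 ± 0.59) were higher and Cdkn1c was lower (-5.04 ± 0.39), and 6 of 14 genes of the E2F and CDK inhibitor list were higher and 2 lower (camera adjusted p = 0.192). Of 13 p53 targets 7 were higher and 1 lower (camera adjusted p = 0.149), with Mdm2, the p53 ubiquitin ligase, at 3.07 ± 0.27. Of 23 cell cycle genes 1 was called, cyclin E2 (Ccne2, -3.08 ± 0.63; camera adjusted p = 0.606). The remaining lists were not called by camera. Of their tested genes, 1 was higher and 0 lower among 7 mesothelium genes (Wt1, 3.35 ± 0.60), 0 and 2 among 5 adipocyte genes, 0 and 2 among 7 skeletal muscle genes, 4 and 2 among 14 heat shock genes, 4 and 3 among 17 interferon response genes, 0 and 4 among 21 respiratory chain genes, 4 and 3 among 13 immediate early genes, 3 and 3 among 14 receptor tyrosine kinase genes and 1 and 2 among 10 neural stem genes. These counts were the same when adjusted over the list alone, except that 2 interferon genes were then lower. The single blood gene tested, Alas2, was lower (-1.54 ± 0.29). For neural stem genes the median was 0.11 and the mean -0.85.

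The tsA58 line was compared with tsA58 stomach muscle in the same way. It too had lower levels of most listed genes of contractile, neural and epithelial cells, and it had higher levels of most listed cell cycle and interferon response genes. With an estimated correlation the adjusted p of these 5 lists was 0.110 to 0.227. The myosin light chain Myl9 (-10.40 ± 0.23, adjusted p = 3.98e-10), Actg2 (-9.61 ± 0.18), Myh11 (-9.21 ± 0.19) and Vip (-8.47 ± 0.18) were the furthest down among those named. Mmp13 (8.43 ± 0.23), the chromatin protein Hmga2 (6.31 ± 0.33), the chemokine Cxcl10 (6.26 ± 0.29) and the ISG15 protease Usp18 (5.95 ± 0.67) were the furthest up. In all, 4214 genes were called, 1698 higher and 2516 lower. That balance turned with quantile normalisation (2210 and 2109) and with centring on the hybridisation controls (1821 and 1151).

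All 23 cell cycle genes tested were higher in the tsA58 line than in its tissue, over all genes and when adjusted over the list alone (median 2.80; camera adjusted p = 1.40e-09, but adjusted p = 0.227 with an estimated correlation), with the mitotic kinase Bub1 at 4.61 ± 0.89, ribonucleotide reductase Rrm2 at 4.48 ± 0.96 and topoisomerase Top2a at 4.47 ± 0.96. Interferon response genes were higher in 14 of 17 (14 when adjusted over the list alone; median 3.04; adjusted p = 0.227 with an estimated correlation). Of 13 p53 targets 7 were higher and 1 lower (7 and 2 when adjusted over the list alone; adjusted p = 0.110 with an estimated correlation), including the CDK inhibitor Cdkn1a (2.79 ± 0.20) and Mdm2 (3.88 ± 0.24). The E2F and CDK inhibitor list had 8 higher and 2 lower of 14 (the same when adjusted over the list alone; camera adjusted p = 0.041, but adjusted p = 0.290 with an estimated correlation), with Cdkn2a at 3.91 ± 0.39. That call ended without tsA58 line replicate 3 (adjusted p = 0.099). Cholesterol synthesis genes were higher in 9 of 15 (9 when adjusted over the list alone; adjusted p = 0.312 with an estimated correlation), with the demethylase Cyp51 at 2.70 ± 0.25.

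Smooth muscle genes were lower in all 20 tested and enteric neuron genes in all 18 in the tsA58 line, also when adjusted over the list alone (medians -5.20 and -5.01; adjusted p = 0.110 with an estimated correlation for each). Glial genes were lower in 9 of 11 and endothelial genes in 11 of 12, the same when adjusted over the list alone (adjusted p = 0.110 and adjusted p = 0.148 with an estimated correlation). Macrophage and leukocyte genes were lower in 13 of 17 (13 lower and 1 higher when adjusted over the list alone; adjusted p = 0.207 with an estimated correlation), with the complement genes C1qa at -5.67 ± 0.33 and C1qb at -5.97 ± 0.35. Of 17 gastric epithelial genes 15 were lower and 1 higher, also when adjusted over the list alone (adjusted p = 0.227 with an estimated correlation). Of 19 fibroblast and matrix genes 12 were lower and 1 higher (13 and 1 when adjusted over the list alone; adjusted p = 0.207 with an estimated correlation). Adipocyte genes were lower in 4 of 5, Wnt and hedgehog genes in 6 of 12 and respiratory chain genes in 6 of 21, the same when adjusted over the list alone (adjusted p = 0.332, adjusted p = 0.110 and adjusted p = 0.227 with an estimated correlation). The respiratory chain call ended when arrays were centred on the hybridisation controls (adjusted p = 0.088). Mesothelium genes were lower in 3 of 7 (4 when adjusted over the list alone), with camera adjusted p = 0.204.

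Of 9 mature ICC markers, 8 were lower in the tsA58 line, also when adjusted over the list alone (median -2.46; adjusted p = 0.110 with an estimated correlation). Kit was at -4.36 ± 0.33, Ano1 at -2.68 ± 0.33, and the calcium channel Cacna1h at -3.48 ± 0.39. Kitl (-2.26 ± 0.23) and Pdgfra (-3.31 ± 0.55) were lower, and the hyaluronan receptor Cd44 was higher (2.65 ± 0.26). Cd34 (0.76 ± 0.32), Insr (-0.08 ± 0.39) and Igf1r (0.36 ± 0.32) were not called, and Insr turned to 0.51 under hybridisation control centring. Cd34 was called without tsA58 line replicate 2 (1.15). Glycolysis genes were 5 higher and 1 lower of 17 (camera adjusted p = 0.072). Heat shock genes were 5 higher and 3 lower of 14, with a median of 0.51 and a mean of -0.03 (camera adjusted p = 0.201), and the inducible Hspa1a was lower (-4.15 ± 0.26).

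**Figure D2:**
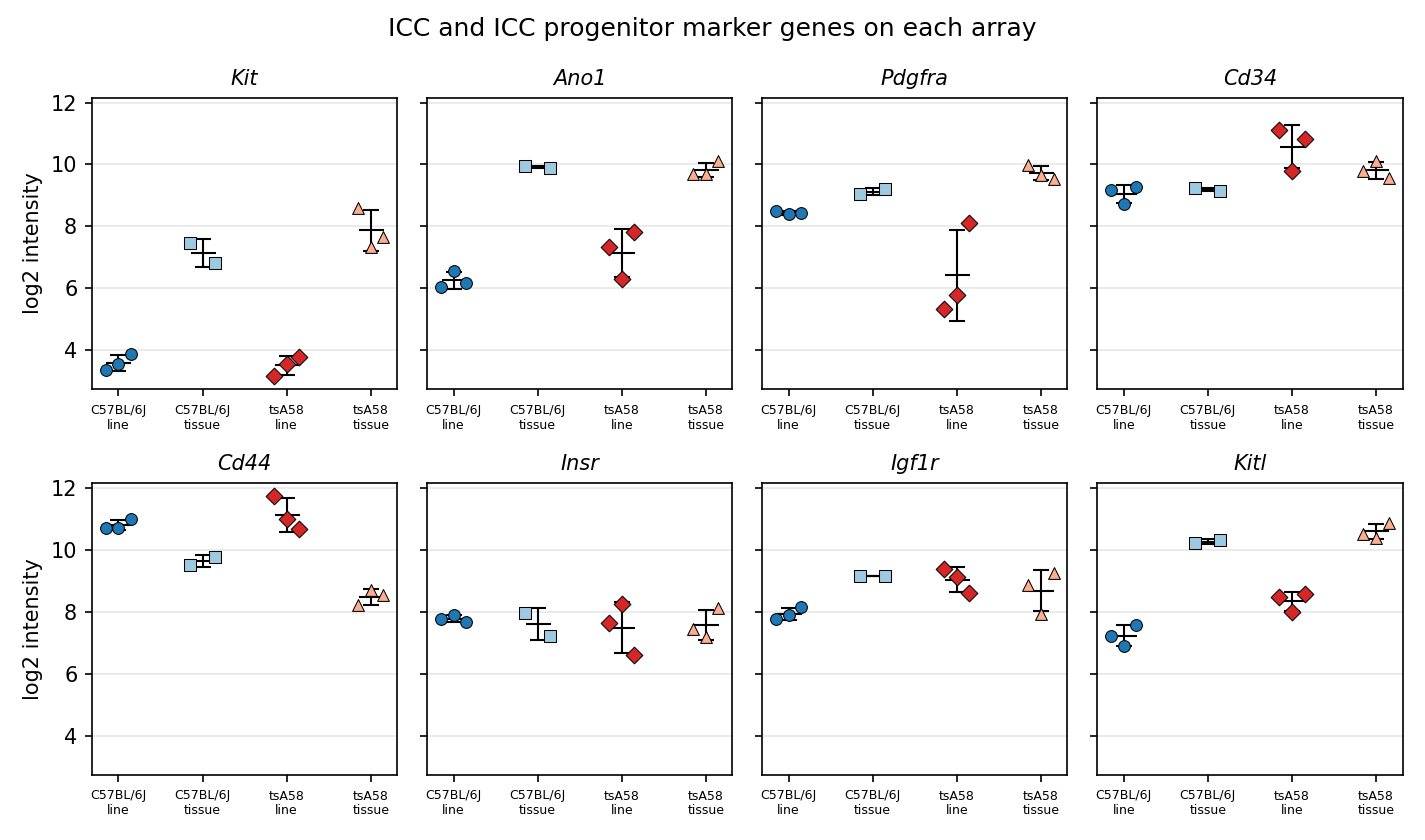
Log2 intensity (y axis) of 8 marker genes of ICC and their progenitors in the 4 groups (x axis); points are arrays, the horizontal mark and bar are the group mean and SD. Kit lies at 3.60 ± 0.26 in the C57BL/6J line and 3.51 ± 0.32 in the tsA58 line, below its levels in the tissues, 7.15 ± 0.45 and 7.87 ± 0.66.

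Across the 13285 genes, the fold changes of the line-tissue comparisons of both strains, which share no array, correlated at r = 0.685 (Spearman 0.599); genes are not independent replicates, so no p-value is given. Called higher in both were 771 genes, against 297.3 for independent lists, and called lower in both 1465, against 417.4. Opposite calls were made for 109 genes, against 722.2. Actg2, Myh11, Vip and Tac1 were lower in both and Mmp13 was higher in both.

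The lines were compared with each other, where strain, transgene, temperature, clone and the medium named in the labels differ together. The tsA58 line had higher levels of most listed interferon response and cell cycle genes, lists that lost their calls with an estimated correlation (adjusted p = 0.550 and 0.833). The interferon-induced surface protein Ly6e stood at 12.97 ± 0.13 in the tsA58 line and 3.20 ± 0.28 in the C57BL/6J line (9.76 ± 0.50, adjusted p = 1.50e-06, n = 3 in each line), and Usp18 (6.58 ± 0.67), Rtp4 (6.10 ± 0.58), the GTPase Iigp1 (5.90 ± 0.64) and Ifit3 (4.93 ± 0.66) were also higher. The other Ly6e probe set gave 3.84 and was called. The imprinted non-coding RNA Meg3 (-7.34 ± 0.50), Myl9 (-5.83 ± 0.23) and the synaptic protein gene Snap25 (-5.10 ± 0.27) were lower. In all, 1880 genes were called, 1113 higher and 767 lower (7582 and 96 with centring on the hybridisation controls, 2159 and 1054 with the 3' to 5' ratio as a covariate).

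Of 17 interferon response genes 16 were higher in the tsA58 line, also when adjusted over the list alone (median 3.27; camera adjusted p = 6.12e-15, but adjusted p = 0.550 with an estimated correlation). Of 23 cell cycle genes 14 were higher (17 when adjusted over the list alone; median 2.03; adjusted p = 0.833 with an estimated correlation), for example the replication helicase subunit Mcm5 (3.67 ± 0.61) and Ccne2 (3.22 ± 0.56). Rrm2 was higher (3.56 ± 0.96), a call that ended without C57BL/6J line replicate 1 (3.31, adjusted p = 0.086) or 2 (3.24, adjusted p = 0.080), or tsA58 line replicate 1 (3.59, adjusted p = 0.065) or 2 (3.70, adjusted p = 0.052). Of 13 p53 targets 6 were higher and 1 lower, also when adjusted over the list alone (adjusted p = 0.550 with an estimated correlation), with Trp53inp1 at 2.33 ± 0.50, cyclin G1 (Ccng1) at 1.85 ± 0.26 and the apoptosis gene Pmaip1 at -2.70 ± 0.28. The p53 list lost its call under hybridisation control centring (adjusted p = 0.071).

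Mesothelium genes were lower in 4 of 7 in the tsA58 line (5 when adjusted over the list alone; median -2.50; camera adjusted p = 0.012, but adjusted p = 0.833 with an estimated correlation), with keratin 7 (Krt7) at -3.03 ± 0.45 and Wt1 at -2.50 ± 0.54. Without tsA58 line replicate 2 the adjusted p was 0.072. Replicate 3 of the tsA58 line averaged 9.38 over that list, against 6.76 and 6.05 for replicates 1 and 2. Smooth muscle genes were 3 lower and 1 higher of 20 (4 and 1 when adjusted over the list alone; camera adjusted p = 0.015, but adjusted p = 0.833 with an estimated correlation), which ended without tsA58 line replicate 2 (adjusted p = 0.110). Glycolysis genes were lower in 3 of 17, also when adjusted over the list alone (camera adjusted p = 0.015, but adjusted p = 0.833 with an estimated correlation), with Aldoc at -4.52 ± 0.79 and Slc16a3 at -3.03 ± 0.39. That call ended without C57BL/6J line replicate 3 (adjusted p = 0.083) or tsA58 line replicate 2 (adjusted p = 0.303). By fry the mesothelium and glycolysis lists were not called (adjusted p = 0.092 and 0.111). The smooth muscle and glycolysis medians, -0.32 and -0.50, turned to 1.17 and 0.99 under hybridisation control centring. Other lists were not called. Among their genes the Wnt modulators Dkk3 (-3.88 ± 0.32) and Sfrp2 (3.21 ± 0.43) and the growth factor Igf2 (-3.42 ± 0.50) were called. Heat shock genes were called in both directions, with Hspb1 lower (-3.003, other probe set -3.17, also called) and Hsph1 higher (2.34 ± 0.28).

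Among ICC and progenitor markers, Kit (-0.09 ± 0.33), Ano1 (0.89 ± 0.33), Cd44 (0.33 ± 0.26) and Insr (-0.29 ± 0.39) were not called between the lines, and Kit lay below the array median in both. Under hybridisation control centring Kit and Insr turned to 1.40 and 1.20, and without tsA58 line replicate 2 Ano1 was called (1.32). Of the 2 other Cd44 probe sets, 1 gave 1.26 and was called. The other probe sets of Pdgfra gave -0.69 and -0.67 and those of Igf1r 0.31 to 0.75, with 0 called. Cd34 was higher in the tsA58 line (1.52 ± 0.32). Kitl was higher (1.11 ± 0.23), but lay under the fold limit without C57BL/6J line replicate 2 (0.94) or tsA58 line replicate 3 (1.00). Pdgfra was lower (-2.03 ± 0.55), a call that ended without C57BL/6J line replicate 1, 2 or 3 (adjusted p = 0.077, 0.063 and 0.061, fold changes -1.99, -2.05 and -2.03) or tsA58 line replicate 1 or 2 (-1.49 and -1.72, adjusted p = 0.089 and 0.085). Igf1r was higher (1.10 ± 0.32), which ended without any of the same arrays (1.02, 1.08 and 1.21, then 0.93 and 1.06, adjusted p from 0.0505 to 0.112).

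The tissues were compared to show how the source material differed between strains. tsA58 stomach muscle had higher levels of 7 of 20 smooth muscle genes and lower levels of 4 of 10 neural stem genes, lists that lost their calls with an estimated correlation (adjusted p = 0.872 and 0.346). The adipocyte, endothelial and exocrine pancreas lists were not called by camera, and their levels varied among the tsA58 tissue arrays. Adipocyte genes averaged 7.60 ± 0.02 in C57BL/6J and 9.75 ± 1.78 in tsA58 tissue. Endothelial genes averaged 5.61 ± 0.002 and 6.51 ± 0.41, and exocrine pancreas genes averaged 9.03 ± 3.39 and 7.24 ± 2.80. The intermediate filament desmin (Des, 2.47 ± 0.20, adjusted p = 1.44e-04), the smooth muscle protein smoothelin (Smtn, 2.54 ± 0.44), the potassium channel subunit Kcnmb1 (2.29 ± 0.27), the endothelial adhesion molecule Pecam1 (2.42 ± 0.33) and the fibroblast genes Fbln1 (2.44 ± 0.26) and Thy1 (2.16 ± 0.20) were higher. The other Des probe set gave 0.38 and was not called, and those of Fbln1 gave 0.26 and 1.70. Rpgrip1 (-6.41 ± 0.49), Ang (-5.70 ± 0.33), Prom1 (-2.47 ± 0.36) and Sox2 (-2.14 ± 0.23) were lower. In all, 1696 genes were called, 1270 higher and 426 lower. The count fell to 817 without C57BL/6J tissue replicate 1 and 853 without replicate 2, each of which leaves 1 array that is taken to vary like the other groups. With centring on the hybridisation controls 12185 genes were called, 12167 of them higher.

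Smooth muscle genes were higher in 7 of 20 in tsA58 tissue and lower in 1, also when adjusted over the list alone (camera adjusted p = 0.010, but adjusted p = 0.872 with an estimated correlation), a list call that ended without tsA58 tissue replicate 3 (adjusted p = 0.092). Neural stem genes were lower in 4 of 10, also when adjusted over the list alone (camera adjusted p = 0.0044, but adjusted p = 0.346 with an estimated correlation), and cholesterol synthesis genes were 3 lower and 1 higher of 15, also when adjusted over the list alone (camera adjusted p = 0.0044, but adjusted p = 0.872 with an estimated correlation). Cell cycle genes had a median of -1.02, with 2 of 23 lower (1 when adjusted over the list alone; camera adjusted p = 2.73e-07, but adjusted p = 0.872 with an estimated correlation). Those medians of -0.23, -0.54 and -1.02 turned to 1.90, 1.59 and 1.10 under hybridisation control centring. By fry the cell cycle and cholesterol synthesis lists were not called (adjusted p = 0.175 and 0.288). Cell cycle genes averaged 7.82 on tsA58 tissue replicate 1 and 6.20 and 5.61 on replicates 2 and 3, against 8.02 and 7.98 on the C57BL/6J tissue arrays. The 2 lower members were Rrm2 (-3.50 ± 1.08) and Ccne2 (-2.32 ± 0.63). The 2 other Rrm2 probe sets gave -2.06 and -0.78 and were not called. Rrm2 lost its call without any 1 of the 8 arrays C57BL/6J line replicates 1 and 2 (-3.50 each, adjusted p = 0.062 and 0.059), C57BL/6J tissue replicates 1 and 2 (-3.51 and -3.49, adjusted p = 0.178 and 0.177), tsA58 line replicates 1 and 2 (-3.50 each, adjusted p = 0.061 and 0.055) and tsA58 tissue replicates 2 and 3 (-3.18 and -2.46, adjusted p = 0.093 and 0.108). Ccne2 lost it without C57BL/6J tissue replicates 1 or 2 (-2.38 and -2.26, adjusted p = 0.125 and 0.138) or tsA58 tissue replicates 2 or 3 (-1.97 and -2.04, adjusted p = 0.064 and 0.078).

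The gastric protease chymosin (Cym), a milk-clotting enzyme, was lower in tsA58 tissue (-6.85 ± 1.95), with levels of 14.15 and 14.11 on the C57BL/6J tissue arrays and 12.87, 5.03 and 3.94 on tsA58 tissue replicates 1, 2 and 3. That call ended without C57BL/6J line replicate 1 (-6.85, adjusted p = 0.0503), C57BL/6J tissue replicate 1 or 2 (-6.84 and -6.87, adjusted p = 0.150 and 0.146) or tsA58 tissue replicate 2 or 3 (-5.73 and -5.19, adjusted p = 0.077 and 0.087). Kit (0.72 ± 0.37), Pdgfra (0.61 ± 0.62), Cd34 (0.62 ± 0.35), Insr (-0.02 ± 0.44), Igf1r (-0.49 ± 0.35), Kitl (0.33 ± 0.26) and Ano1 (-0.09 ± 0.37) were not called between tissues, although the other Ano1 probe set gave 1.24 and was called, and those of Igf1r ranged from -1.19 to 0.23 with 1 called lower. When arrays were centred on the hybridisation controls, Ano1, Insr, Igf1r and Cd44 turned to 2.04, 2.10, 1.64 and 0.97, and under median centring Insr turned to 0.06. Cd44 was lower (-1.15 ± 0.29), while 2 other probe sets gave 0.34 and 0.89, and the call ended without C57BL/6J tissue replicate 1 or 2 (-1.29 and -1.02, adjusted p = 0.082 and 0.148) or tsA58 tissue replicate 1 (-1.02, adjusted p = 0.052). Adiponectin (Adipoq), an adipocyte hormone, was higher (3.93 ± 0.95), which ended without C57BL/6J tissue replicate 1 or 2 (3.89 and 3.98, adjusted p = 0.104 and 0.095) or tsA58 tissue replicate 3 (3.48, adjusted p = 0.053).

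Fold changes between the lines and between the tissues, which share no array, correlated at r = 0.003 (Spearman 0.020) across the 13285 genes. The lines differ in more than strain, and the tissue arrays are of mixed sex. This correlation therefore does not tell whether strain effects are shared. Called higher in both were 120 genes, against 106.4 for independent lists, called lower in both 52, against 24.6, and opposite 125, against 109.0.

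Whether the line-tissue difference itself differed between strains was tested as the tsA58 difference minus the C57BL/6J difference. Most listed interferon response and cell cycle genes differed upward, and 10 of 20 smooth muscle genes downward. These lists lost their calls with an estimated correlation (adjusted p = 0.484, 0.484 and 0.549). Ly6e (10.11 ± 0.75, adjusted p = 5.51e-05), Usp18 (6.70 ± 1.01), Rrm2 (7.07 ± 1.45) and Ccne2 (5.54 ± 0.84) were among the largest positive values, and Myl9 (-6.78 ± 0.35), the matrix protein Mgp (-6.91 ± 0.67), Dkk3 (-5.51 ± 0.48) and Snap25 (-5.33 ± 0.41) among the largest negative. The other Ly6e probe set gave 4.19 and was called. In all, 2702 genes were called, 970 positive and 1732 negative (127 and 450 with centring on the hybridisation controls, 1239 and 1342 with quantile normalisation). Without C57BL/6J tissue replicate 1 or 2 the count was 1485 or 1505.

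Of 23 cell cycle genes 22 were called positive (23 when adjusted over the list alone; median 3.09; camera adjusted p = 4.80e-14, but adjusted p = 0.484 with an estimated correlation), and of 17 interferon response genes 13 (14 when adjusted over the list alone; median 2.92; adjusted p = 0.484 with an estimated correlation). Smooth muscle genes were negative in 10 of 20 (12 negative and 1 positive when adjusted over the list alone; median -1.40; adjusted p = 0.549 with an estimated correlation). Of 13 p53 targets 2 were positive, also when adjusted over the list alone (camera adjusted p = 0.023, but adjusted p = 0.484 with an estimated correlation). Glycolysis genes were negative in 7 of 17 (8 when adjusted over the list alone; camera adjusted p = 0.023, but adjusted p = 0.709 with an estimated correlation). That call ended without C57BL/6J line replicate 3 (adjusted p = 0.060), tsA58 line replicate 2 (adjusted p = 0.106) or tsA58 tissue replicate 2 (adjusted p = 0.056). Kit (-0.81 ± 0.49), Ano1 (0.98 ± 0.50), Cd34 (0.90 ± 0.48), Insr (-0.26 ± 0.58) and Kitl (0.78 ± 0.35) were not called, while without tsA58 line replicate 2 Ano1 (1.41) and Cd34 (1.30) were. The other Kit probe set gave -1.12 and was called, that of Ano1 gave -0.42, and those of Kitl ranged from -0.85 to 0.25. The 2 other Cd44 probe sets gave -0.21 and 0.38 and were not called. Pdgfra was negative (-2.64 ± 0.83), a call that ended on leaving out any 1 array other than tsA58 line replicate 3 (-2.73 to -2.10, adjusted p from 0.061 to 0.130). Cd44 (1.48 ± 0.39) lost its call without C57BL/6J line replicate 1 or 2 (1.43 each, adjusted p = 0.057 and 0.051) or C57BL/6J tissue replicate 1 or 2 (1.61 and 1.35, adjusted p = 0.058 and 0.098). Igf1r (1.59 ± 0.47) lost it without any C57BL/6J array (1.51, 1.57, 1.69, 1.59 and 1.59, adjusted p from 0.0502 to 0.107) or tsA58 line replicate 1 or 2 (1.41 and 1.55, adjusted p = 0.082 and 0.064).

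**Figure D3:**
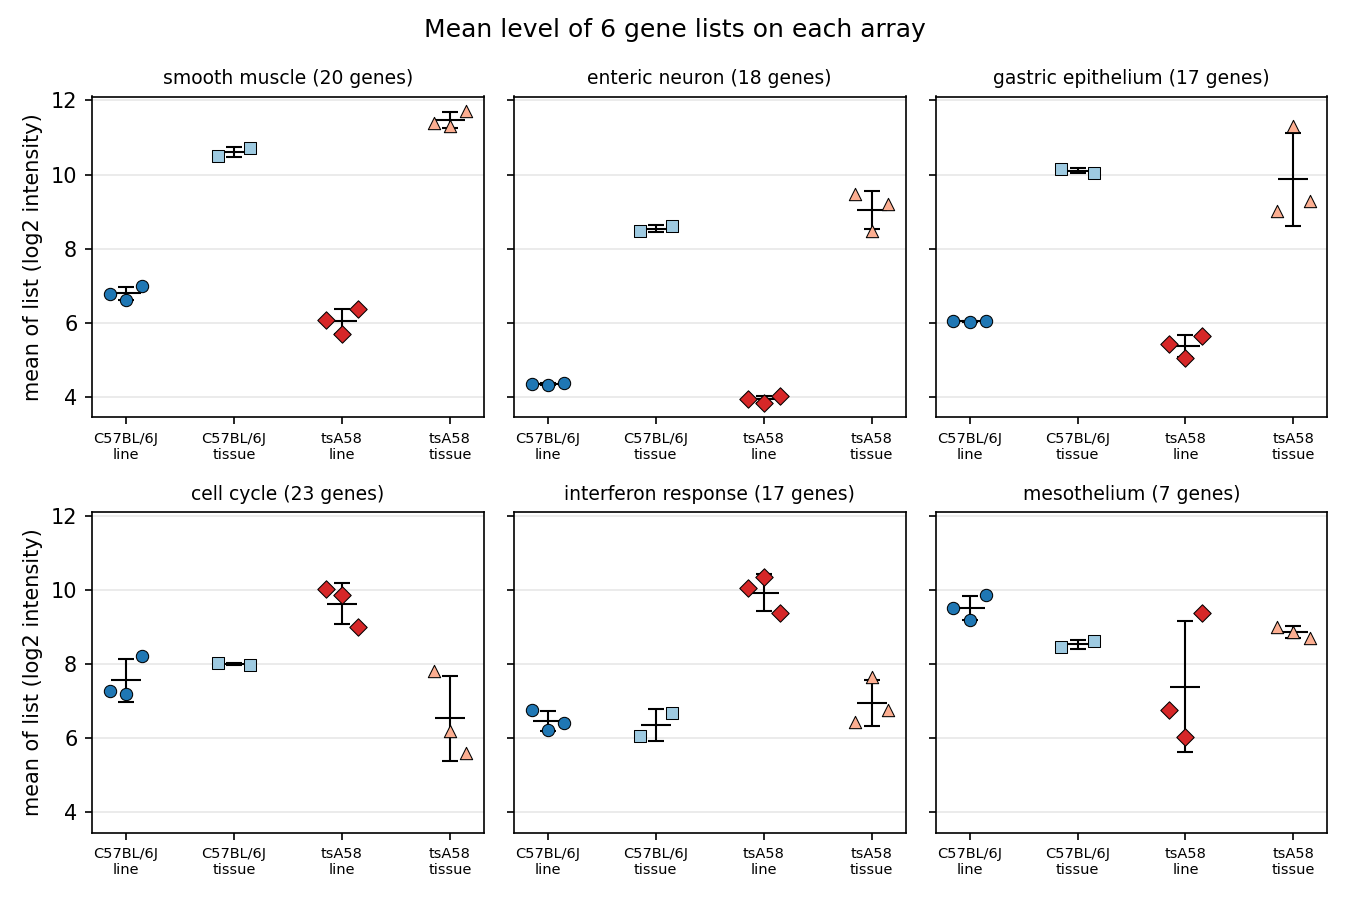
Mean log2 intensity (y axis) of 6 gene lists on each array, by group (x axis); points are arrays, the horizontal mark and bar are the group mean and SD. The interferon response list lies at 9.93 ± 0.50 in the tsA58 line and between 6.37 and 6.96 in the other groups, and the mesothelium list spreads over 7.40 ± 1.76 in the tsA58 line.

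Sex-linked transcripts differed between the lines. Xist, the RNA of the inactive X chromosome, stood at 11.64 ± 0.08 in the C57BL/6J line and 4.99 ± 0.08 in the tsA58 line (-6.65 ± 1.26). The Y-linked genes Eif2s3y (4.72 ± 1.29), Kdm5d (3.81 ± 0.85) and Uty (1.56 ± 0.42) were higher in the tsA58 line. These standard errors rest on a spread shared with the tissues. Eif2s3y had an SD of 0.11 in the C57BL/6J line, 0.40 in the tsA58 line and 3.58 in tsA58 tissue. Xist had 3.29 and 2.64 in C57BL/6J and tsA58 tissue. The lost calls below thus do not measure the spread within the lines. The Eif2s3y call ended without any C57BL/6J line replicate (4.78, 4.67 and 4.71, adjusted p = 0.071, 0.069 and 0.063) or tsA58 line replicate 1 or 2 (4.95 and 4.58, adjusted p = 0.058 and 0.069). The Uty call ended without any C57BL/6J line replicate (1.43, 1.61 and 1.63, adjusted p = 0.089, 0.057 and 0.0504) or tsA58 line replicate 2 (1.55, adjusted p = 0.060). In C57BL/6J tissue, replicate 1 had Xist at 10.12 and Eif2s3y at 7.91, and replicate 2 had 5.47 and 8.09, so replicate 1 held both signals. Whether it came from more than 1 animal was not determined. In tsA58 tissue, Xist was 4.83, 9.32 and 4.66 and Eif2s3y 8.87, 2.92 and 9.35 on replicates 1, 2 and 3, so arrays of a group did not hold tissue of 1 sex. Against tissue, the C57BL/6J line had Xist at 3.84 ± 1.41, Eif2s3y at -4.88 ± 1.44, Kdm5d at -2.78 ± 0.95 and Uty at -0.52 ± 0.47. The other Xist probe set gave 0.22 and was not called, and those of Uty gave -3.19 and -1.91, 1 of them called. The Xist call ended without any C57BL/6J line replicate (3.87, 3.79 and 3.86), C57BL/6J tissue replicate 2 (1.52) or any tsA58 line replicate (3.84 each, adjusted p from 0.053 over all these to 0.460). That of Eif2s3y ended without tissue replicate 1 or 2 (-4.97 and -4.79, adjusted p = 0.076 and 0.086), and that of Kdm5d without any C57BL/6J array (-2.74, -2.76, -2.85, -2.80 and -2.76, adjusted p from 0.063 to 0.126).

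Xist (-1.28 ± 1.26), Eif2s3y (0.79 ± 1.29), Kdm5d (1.10 ± 0.85) and Uty (0.73 ± 0.42) were not called in the tsA58 line against tissue. Between tissues, Xist (-1.53 ± 1.41), Eif2s3y (-0.95 ± 1.44), Kdm5d (-0.07 ± 0.95) and Uty (0.30 ± 0.47) were not called, although another Uty probe set was called at -2.74. Without tsA58 tissue replicate 2, Eif2s3y was called at -1.27 in the tsA58 line against tissue, and Eif2s3y and Kdm5d at 1.11 and 1.28 between tissues. Under hybridisation control centring Xist, Eif2s3y and Kdm5d turned to 0.60, 1.18 and 2.06 between tissues, and Uty turned to 0.71 in the C57BL/6J line against tissue. Under median centring Kdm5d turned to 0.01 between tissues. In the difference of differences, Xist (-5.12 ± 1.89), Eif2s3y (5.67 ± 1.94), Kdm5d (3.88 ± 1.27) and Uty (1.26 ± 0.63) were not called, although with Nnt 3 of the 5 check genes were positive and 1 negative when adjusted over the list alone, and 2 other Uty probe sets gave 2.46 and 3.64, 1 of them called. There Xist was called without C57BL/6J tissue replicate 1 (-7.44), and Eif2s3y and Kdm5d without any 1 of the tsA58 tissue replicates (6.58, 3.61 and 6.82, and 4.53, 2.53 and 4.57).

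Nnt, a mitochondrial transhydrogenase gene that carries a deletion in C57BL/6J mice, stood at 7.45 ± 0.29 in the C57BL/6J line, 9.31 ± 0.01 in C57BL/6J tissue, 9.60 ± 0.24 in the tsA58 line and 9.63 ± 0.26 in tsA58 tissue. It was lower in the C57BL/6J line than in its tissue (-1.86 ± 0.23), higher in the tsA58 than the C57BL/6J line (2.15 ± 0.21), positive in the difference of differences (1.83 ± 0.31), and not called in the tsA58 line against tissue (-0.03 ± 0.21, which turned to 0.04 under median centring and 0.56 under hybridisation control centring) or between tissues (0.32 ± 0.23, with another probe set at -0.36). Where its probe set lies relative to the deletion was not determined here, so its level does not check the strain labels.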

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

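The tests of leukocytes, of single arrays and of a strain difference behind the interferon pattern, and the tests of mucosa and sex behind the tissue pattern, were chosen after the result was seen. The test of younger animals was written before it.

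The line-tissue difference of tsA58 and that of C57BL/6J were set apart by limma's test of the difference between them for 2702 genes. Of the gene lists, cell cycle (median 3.09), interferon response (2.92), p53 targets (0.806), glycolysis (-0.972) and smooth muscle (-1.40) differed by camera at the preset correlation, and 0 lists did with an estimated correlation. At an unadjusted p under 0.05 the estimated correlation left 1 list, and fry called 12.

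Interferon response genes were higher in the tsA58 line, with line-minus-tissue differences of 6.70 for Usp18, 4.66 for Ifit1 and 4.13 for Gbp3. Ly6e, which is outside that list, gave 10.11, and its other probe set 4.19. Leukocytes in the culture would raise leukocyte genes too, but the median of the 17 tested was -0.248 between lines. That list averaged 4.82 in the C57BL/6J line and 4.57 in the tsA58 line, near the array median, so a small share of leukocytes is not excluded. Of its members Cd74 was called higher (2.15) and Csf1r lower (-2.27). A single array does not carry the pattern, since 17 of the 17 list genes were higher on all 3 tsA58 line arrays than on all 3 C57BL/6J line arrays. By chance that has a share of 5% for a gene. The genes can vary together and most had been called from these same arrays, so it adds no evidence for the pattern. A strain difference of the same size in tissue would put the list near its line median of 3.27 between tissues too, where the median was 0.57. The median difference of differences, 2.92, is the value that set the list apart, rests on the same fold changes and is no further evidence. The tissue median speaks only against a strain difference of like size in whole tissue. A strain effect confined to cells like those of the line was not tested. Such a strain effect, the transgene, the temperature of 39.5 °C, the medium, the clone and its sex cannot be told apart here. Array processing may differ with the line too. The log2 actin 3' to 5' ratio was 0.47 in the tsA58 line and 1.02 in the C57BL/6J line. Hybridisation controls averaged 8.14 and 9.63. The labels name chick embryo extract in the C57BL/6J line alone and state that interferon-gamma was left out for the tsA58 line.

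Cell cycle genes had line-minus-tissue differences of 7.07 for Rrm2, 5.54 for Ccne2 and 5.17 for Bub1, the last not called without C57BL/6J tissue replicate 1 or 2 (5.17 each, adjusted p = 0.070 and 0.071). Between tissues the list had a median of -1.02, which turned to 1.10 under hybridisation control centring, with 2 of 23 genes called lower in tsA58 tissue (adjusted p = 0.872 with an estimated correlation). Rrm2, Ccne2 and the protease gene Cym lost those calls without C57BL/6J tissue replicate 1 (-3.51, -2.38 and -6.84) or 2 (-3.49, -2.26 and -6.87) or tsA58 tissue replicate 2 (-3.18, -1.97 and -5.73) or 3 (-2.46, -2.04 and -5.19). Rrm2 lost it also without C57BL/6J line replicate 1 or 2 or tsA58 line replicate 1 or 2 (-3.50 each), and Cym without C57BL/6J line replicate 1 (-6.85). Cell cycle genes and Cym were higher on tsA58 tissue replicate 1 than on replicates 2 and 3. Gastric epithelium genes averaged 9.01, 11.30 and 9.30 on replicates 1, 2 and 3, lowest on replicate 1 and highest on replicate 2. For these arrays the values argue against more mucosa on replicate 1, as far as that list measures it. The bound written against mucosa, replicate 1 below the mean of replicates 2 and 3, was met (-1.29), although replicate 2 carries that gap. As run, the test asked for more than 1 below both, which was not met. Between strains mucosa left on the muscle stays open, with gastric epithelium genes at 10.16 and 10.05 on the C57BL/6J tissue arrays. Sex is argued against by replicates 1 and 3, which had like Xist and Y-linked signals while Cym differed by 8.93. Younger animals stay a hypothesis for the C57BL/6J samples and that replicate: 9 imprinted growth genes had a median of -0.633 between tissues and all 9 were higher on replicate 1 (median 1.29), although 1 was called lower and 0 higher. Hybridisation control centring moved fold changes between tissues by 2.13, more than that median, so its sign depends on the scaling. Replicate 1 also had the lowest hybridisation controls of the tsA58 tissue arrays (7.52, against 9.04 and 9.66 on replicates 2 and 3). The labels give no ages.

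Other genes set apart by the same test are given as values. Contractile and neural genes were Myl9 (-6.78), Smtn (-2.88), Cnn1 (-2.86) and Snap25 (-5.33), and other markers Snai2 (5.01), Mgp (-6.91), Krt8 (-3.23), Dkk3 (-5.51) and Sfrp2 (3.72). The p53 targets were Ccng1 (1.53) and Bbc3 (1.29), the glycolysis genes Aldoc (-4.91), Slc16a3 (-2.63) and Aldoa (-2.03), and the heat shock genes Hspb1 (-4.57) and Hsph1 (1.53). Receptors and strain genes were Pdgfra (-2.64), Cd44 (1.48), Igf1r (1.59) and Nnt (1.83). Without C57BL/6J tissue replicate 1 the calls of Cnn1 (-2.79), Ccng1 (1.39), Bbc3 (1.09), Aldoc (-4.72), Hsph1 (1.52), Pdgfra (-2.56), Cd44 (1.61) and Igf1r (1.59) ended, and without replicate 2 those of Ccng1 (1.67), Aldoc (-5.09), Hsph1 (1.54), Pdgfra (-2.71), Cd44 (1.35) and Igf1r (1.59). Hsph1 also lost its call without C57BL/6J line replicate 1 or 2 (1.53 and 1.34) or tsA58 tissue replicate 3 (1.44). Pdgfra did so without any 1 of the other arrays except tsA58 line replicate 3 (-2.73 to -2.10), Cd44 without C57BL/6J line replicate 1 or 2 (1.43 each), and Igf1r without any C57BL/6J line replicate (1.51, 1.57 and 1.69) or tsA58 line replicate 1 or 2 (1.41 and 1.55).

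Probe sets with several gene names or none lie outside the gene comparisons, and of the 3419 above the filter 976 were called in the C57BL/6J line against tissue, 825 in the tsA58 line against tissue, 451 between lines, 630 between tissues and 776 in the difference of differences.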

How the results depend on the processing

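Leaving out 2 arrays that stood apart, tsA58 line replicate 3 and tsA58 tissue replicate 1, was chosen after the data were seen. For the 260 gene results, 6433 alternative values were computed: 6028 kept direction and side of the thresholds, 302 lost the call, 32 gained it, 17 turned past the threshold or from a called value, and 54 changed sign without a call. Of the 2860 with 1 array left out, 2650 kept both. The arrays are few, signal near the array median cannot be told from background, and leaving out a C57BL/6J tissue array leaves 1, which is assumed to vary like the other groups. Unless said otherwise, the cause of a change was not tested.

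In the order C57BL/6J line against tissue, tsA58 line against tissue, lines, tissues and difference of differences, the counts of called genes were 4530, 4214, 1880, 1696 and 2702. Testing each probe set, which adds features, gave 9168, 8192, 3828, 4270 and 6007. A null of 2-fold change, a stricter question, gave 1801, 1808, 342, 62 and 323. With no fold limit the counts were 6356 in the tsA58 line against tissue, 3071 between lines and 2696 between tissues. The 3' to 5' covariate gave 3213 between lines, where 325 of the 1880 calls were lost; between tissues 758 of 1696 were lost, and 25 of the 260 gene results lost their call. Leaving out 1 array gave 3894 to 4644, 3947 to 4551, 1350 to 2680, 817 to 1912 and 1485 to 3700. Leaving out the 2 arrays gave 4725, 4721, 2760, 2069 and 3968. Genes called the same way in both line-tissue comparisons numbered 2236 and ranged from 1847 to 2304.

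Centring on the hybridisation controls shifts all genes of an array, and those controls differed between groups; it gave 5871 (5148 higher, 723 lower, against 2326 and 2204), 2972 (1821 and 1151, against 1698 and 2516), 7678 (7582 and 96, against 1113 and 767), 12185 (12167 and 18, against 1270 and 426) and 577 (127 and 450, against 970 and 1732). Quantile normalisation gave 2210 higher and 2109 lower in the tsA58 line against tissue, 907 and 724 between tissues, and 1239 and 1342 in the difference of differences. Cyclic loess gave 739 and 600 between tissues, 1273 and 1309 in the difference of differences, and 1809 and 2469 in the C57BL/6J line against tissue, where median centring gave 2717 and 1988. The median fold change moved by 0.123 in the C57BL/6J line against tissue with median centring, by 0.206, -0.168 and 0.142 with quantile normalisation in the 3 comparisons named with it, and by -0.164 between tissues and 0.144 in the difference of differences with cyclic loess.

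With an estimated correlation, 0 of the 43 camera calls of lists remained and 15 lists had an unadjusted p under 0.05. Since it called 0 of 125 tests, it does not separate lists that change from others. Fry called 58 of 125, in the same order of comparisons 18, 18, 5, 5 and 12. It left out 4 camera calls: mesothelium and glycolysis between lines (fry adjusted p = 0.092 and 0.111), and cell cycle and cholesterol synthesis between tissues (fry adjusted p = 0.175 and 0.288). Values that turned from a called value or to one under hybridisation control centring were Igf1r in the C57BL/6J line against tissue (0.000134), Kit between lines (1.40), and between tissues Fabp7 (0.123), Cdh1 (0.149), Insig1 (0.145), Cyp51 (0.646), Igf2 (0.184), Ano1 (2.04), Cd44 (0.973), Insr (2.10), Igf1r (1.64) and Kdm5d (2.06). Under that centring 8 more gene results changed sign without a call. Between tissues, Ano1 was 1.24 without probe sets that may bind several transcripts, and Cd44 0.0230 as a mean over probe sets. Leaving out 1 array gave Eif2s3y -1.27 to 1.94 in the tsA58 line against tissue and -2.10 to 1.11 between tissues, and Kdm5d -0.759 to 1.28 there. The turned values came without tsA58 tissue replicate 2, the array with Xist and without Y-linked signal.

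With the replicate number as a block (replicate block), which removes 2 residual degrees of freedom, the counts were 4476, 4202, 1844, 1481 and 2267. Of 15 pairs of arrays with the same number in 2 groups, deviations correlated at -0.156 to 0.250 and 1 pair lay over 0.1, and an array correlated best with its own number in 4 of 18 checks, so the numbers do not pair the arrays. The E2F and CDK inhibitor list in the tsA58 line against tissue had an adjusted p of 0.052 under the block, and the endothelium list between tissues gained a call (adjusted p = 0.045). Of the 260 gene results 12 lost their call under it: Xist in the C57BL/6J line against tissue (4.10), Cym (-6.28), Cdh1 (-1.90), Rrm2 (-3.40), Ccne2 (-2.20), Bst2 (1.46), Igf2 (-1.94) and Cd44 (-1.12) between tissues, and Hsph1 (1.505), Pdgfra (-2.39), Cd44 (1.44) and Igf1r (1.65) in the difference of differences, with adjusted p from 0.055 to 0.081.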

Other observations

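The test of mesothelium-like cells, the test of single probe sets on tsA58 line replicate 3, the test of probe variants and the splits of the arrays were written before their results were seen, and the tests of mixed RNA on that replicate were chosen after.

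Receptor tyrosine kinase genes were not called as a list between the lines. Of the 14 tested 6 were lower and 1 higher in the tsA58 line (6 and 2 when adjusted over the list alone), and camera gave an adjusted p of 0.135 at the preset correlation. The receptor Fgfr1 was lower (-2.13 ± 0.32), as was Csf1r (-2.27 ± 0.38), which encodes the receptor of a macrophage growth factor. The chaperone gene Hsph1 was higher (2.34 ± 0.28), whereas the heat shock gene Hspb1 was lower (-3.003). The inducible Hspa1a was lower in each line than in its tissue (-1.88 ± 0.29 in C57BL/6J and -4.15 ± 0.26 in tsA58). The mesenchymal transcription factor Twist1 was higher in the C57BL/6J line than in its tissue (2.73 ± 0.21).

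Tissue samples differed in what they carried besides muscle. Exocrine pancreas genes averaged 11.43 and 6.63 on C57BL/6J tissue replicates 1 and 2 and 5.24, 10.44 and 6.05 on the tsA58 tissue replicates. Adipocyte genes averaged 7.62 and 7.59 on the C57BL/6J tissue arrays and 7.71, 11.01 and 10.53 on the tsA58 ones. Of 12 endothelial genes 5 were higher in tsA58 tissue and 0 lower, Tie1 at 2.13 ± 0.40 among them (camera adjusted p = 0.061), and of 17 macrophage and leukocyte genes 6 were higher and 2 lower (7 and 2 when adjusted over the list alone; camera adjusted p = 0.407), with C1qb at 2.22 ± 0.39.

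Replicate 3 of the tsA58 line stood apart from replicates 1 and 2, with 181 genes higher and 101 lower by 2 or more. Stomach tissue RNA mixed in is argued against by 12 genes abundant in both tissues, whose median rise was 0.288 (MAD 0.368), although 2 of the 12 rose by more than 1. RNA of the C57BL/6J line met the bound set for it, a median rise above 1 over 6 genes abundant in that line and low on replicates 1 and 2 (2.78, with 3 genes over 1 and 3 not), but that bound was wrong, because mixed RNA brings all abundant transcripts: Meg3 allows a share of at most 0.727% and Xist 1.05%, while Serpinb2 would need 96.9% and Cdh11 52.9%. Noise of single probe sets would move the other probe sets of a gene at random, yet 94.2% of 208 moved the same way; noise of the amplification, which this test was first meant to cover as well, can move a whole transcript and was not tested. Replicate 3 had a log2 actin 3' to 5' ratio of 0.05, against 0.51 and 0.85 on replicates 1 and 2. Its hybridisation controls averaged 7.93, against 8.24 and 8.26. A change of the cells in that culture and a difference in RNA or processing of that array both stay open and were not tested.

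A hypothesis of mesothelium-like cells in the C57BL/6J line came from its high levels of Upk3b (12.26 ± 0.08) and Wt1 (10.42 ± 0.33). A second list of 6 mesothelial genes had a median of -2.61 in that line against tissue, at percentile 0.0400 among 10000 random lists matched on mean level, so this test came out against it by the bound set before. The random genes are not markers of a cell type. The tissue also holds mesothelial signal, so a fall against it does not show that such cells are absent from the line. The list fixed before the data were examined went the other way, with a median of 0.82 (0 of 7 genes lower and 1 higher, not called by camera) and a mean level of 9.52 in that line against 8.54, 7.40 and 8.87 in C57BL/6J tissue, the tsA58 line and tsA58 tissue. On tsA58 line replicate 3 the second list lay 2.20 above replicates 1 and 2.

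Sequence variants under the probes would make genes that differ the same way between strains in lines and in tissues disagree with their other probe sets more often. Such disagreement was seen for 17 of 81 genes (21.0%) called the same way in both, against 238 of 1326 (17.9%) called in 1 (Fisher's exact p = 0.461), which decides nothing.

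The 6 arrays of the tsA58 line and tissue, and the 6 of both lines, can each be split in 10 ways into 3 and 3, too few for a share under 0.05. The real splits called 4214 and 1880 genes by limma and the highest of the others 0 in each case, and at an unadjusted p under 0.05 the real splits gave 7217 and 4885 and the highest of the others 1745 and 1983. Each other split puts arrays of both groups on each side, so the real difference adds to its spread and few calls follow. Those counts are no null level, and nothing is concluded from them.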
